A study of Mus musculus with 2 samples.

How the data were processed

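Gene expression was measured in bone-marrow-derived dendritic cells of C57BL/6 mice, 1 wild-type sample and 1 sample lacking the microRNA miR-155, both treated with lipopolysaccharide (LPS), a bacterial cell wall component that activates innate immune cells. Per the labels' protocols, marrow cells were grown for 7 days with 20 ng/ml of the growth factor GM-CSF, the medium was then replaced by medium with 10 ng/ml LPS, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 ug of it by the standard Affymetrix procedure. The labels call the cells dendritic cells throughout, except for the growth protocol, which names macrophages. The length of the LPS exposure, the number of mice behind each sample and the scanner are not given in the sources used here.

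The authors deposited 1 value table with a linear signal intensity for each of 45101 probe sets on each array, per the file headers and values. The algorithm that made the intensities, detection calls and any scaling are not given in the sources used here. The values were positive and linear, with no centring, and they had no common scale: without the control probe sets, the median intensity was 58.4 on the wild-type array and 78.3 on the knockout array, a gap of 34.1%, and the mean over the probe sets left after trimming 2% at each end was 193.6 and 286.8. A knockout signal was 1.41 times the wild-type signal at the median probe set (0.50 on the log2 scale), and 18 bacterial and phage hybridisation control probe sets had a median log2 difference of 0.33. The rule set before the data were examined called for quantile normalization where the medians differed by more than 10%, so the log2 intensities of the 45037 probe sets other than the 64 controls were quantile normalized. This forces both arrays to one distribution and removes any difference in total signal, real or technical.

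Normalized values under the median of all values (an intensity of 67.6, the floor) were set to it. A gene counted as measured where at least 1 array lay above the floor. Where the other array lay at or below the floor, the difference is a lower bound, written as "at least". The floor is a choice of this work and not a detection call. Gene names came from the platform annotation supplied with the data: 34945 probe sets named 1 gene, 932 named several, and 9160 were unnamed here. Of the 18193 genes so named, 18032 had an identifier in the reference gene table (assembly GRCm38.p6), which was used for names, chromosomes and the order of genes only. A gene with several probe sets was represented by the probe set with the highest mean over both arrays, chosen without regard to the difference; 11878 genes were measured, 10355 of them above the floor on both arrays. Signals given below are normalized intensities, and differences are knockout minus wild type on the log2 scale.

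With 1 array per genotype there is no spread between replicates, so no p-value was computed and differences describe these 2 arrays. Only a size rule was applied (at least 2-fold). The error that can be measured inside the arrays is the disagreement between probe sets of the same gene: over 11653 probe sets of 4410 genes its SD was 0.29 on the log2 scale, and it was 0.34, 0.29 and 0.25 in genes of low, middle and high signal, ranges that hold equal numbers of them. This SD holds no variation between mice or cultures. Each named gene was also placed among the 501 measured genes nearest to it in mean level. The number of arrays limits the precision, and no paired or blocked analysis applies.

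Before the data were examined, 30 gene lists were fixed: reported miR-155 targets, inflammatory and T-cell-polarising cytokines, feedback inhibitors of inflammation, chemokines, interferon-stimulated genes, the NF-kB pathway, co-stimulation and maturation, MHC class II and class I presentation, TLR4 signalling, pattern recognition receptors, prostanoid and oxidant enzymes, markers of dendritic cells, macrophages, granulocytes, mast cells and basophils, T and NK cells, B and plasma cells, erythroid cells, stroma and osteoclasts, proliferation, glycolysis and hypoxia, oxidative phosphorylation, cholesterol synthesis, ribosomal proteins, stress genes, apoptosis, neighbours of the deleted gene and sex-linked transcripts. They were written from general knowledge of these genes. The median difference of a list was placed among those of 10000 random lists of the same size matched on mean level in 20 bins, and a list was said to stand apart where it lay in the outer 5% (both tails together). Were genes independent of one another, chance alone would give 1.4 such lists of the 28 with at least 5 measured members. Here 11 stood apart as lower and 2 as higher. Some genes are in several lists, and 1.4 is not the number that ordinary differences between cultures would give. Members of a list are not independent of one another, so a percentile describes these arrays and is no test between genotypes.

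The genes named were set by a rule fixed before the data were examined: the host transcript of miR-155; 17 genes of interest; the 12 highest and 12 lowest differences among genes above the floor on both arrays; the 4 largest lower bounds each way; and in each list the 3 members with the largest absolute difference, with sex-linked and neighbouring genes past 2-fold. It gave 122 genes. A planned comparison of genes with a miR-155 seed match in their 3' UTR was not run, since 3' UTR sequences were not used here.

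Alternatives were floors at the 25th and 75th percentile and none, centring the deposited values on the median difference, a loess on the mean level, averaging all measured probe sets of a gene, leaving out probe sets whose names end in _x_at or _s_at, thresholds of 1.5-fold and 3-fold, and random lists without matching. The deposited values without scaling and a scaling on the hybridisation controls were added after the data were seen. The steps were tested on simulated arrays with the probe set SD as noise and 200 changed genes among 11523 measured: for the knockout against wild-type comparison, 6.0% of genes changed by 0.6, 78.0% of those changed by 1.2, 82.0% by 2 and 90.0% by 3 log2 units passed the 2-fold rule in the right direction, and 10 of 11323 unchanged genes passed it. In the same simulation 5 of 200 unchanged lists of 20 genes stood apart, and 49 of 50 lists shifted by 0.3 did. The simulated noise held no variation between mice or cultures, so these rates do not give the error rate of the calls on the real arrays. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6.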

Results

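Transcript levels were compared between dendritic cells from miR-155 knockout and wild-type mice after LPS treatment, which addresses how loss of this microRNA alters the gene expression of activated dendritic cells. miR-155 is a small RNA induced by inflammatory signals that represses target transcripts. Each genotype was represented by 1 Affymetrix array, with no replicates and no untreated cells, so the effect of LPS itself was not measured. Depth per array is given by its median intensity, 58.4 for wild type and 78.3 for knockout. All differences below are between those arrays after quantile normalization, so they are relative to the bulk of all genes. Without scaling the knockout was higher by 0.54 at the median measured gene, and by 0.23 with scaling on hybridisation controls. Their only error estimate is the SD of 0.29 log2 units between probe sets of the same gene.

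The host transcript of the deleted microRNA, Mir155hg, had the lowest difference among genes above the floor on both arrays. Its signal was 1136 in wild-type and 159 in knockout cells, 7.13-fold lower, and it stayed above the floor of 67.6 in the knockout; whether its probe set lies in the deleted part is not given in the sources used here. The next measured gene in chromosomal order, Mrpl39, which encodes a mitochondrial ribosomal protein, was 4.13-fold lower (1248 against 302), and 2 of its 2 probe sets were lower. Jam2, a junctional adhesion molecule and the measured gene after it, was at least 2.05-fold lower, again with 2 of 2 probe sets. Bach1, a transcriptional repressor further along the same chromosome and a reported miR-155 target, was 2.26-fold higher at the probe set used (721 against 1631). Its other measured probe set had a difference of -0.28. The 19 measured neighbours in the list fixed beforehand had a median difference of 0.06, at percentile 75.8 of random lists.

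**Figure D1:**
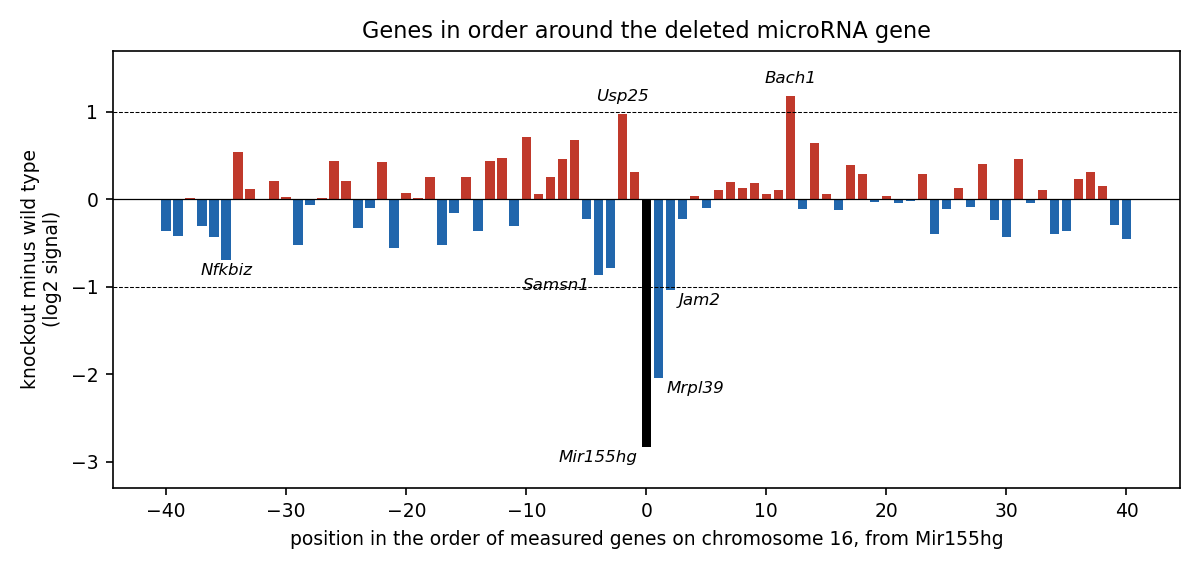
Difference between the knockout and the wild-type array (log2 signal, vertical axis) for measured genes in their order on chromosome 16, with Mir155hg at position 0 (black), higher genes in red, lower genes in blue and dashed lines at 2-fold. Mir155hg (-2.83), Mrpl39 (-2.05) and Jam2 (-1.03, a lower bound) lie side by side.

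Across the 11878 measured genes, 68 were at least 2-fold higher and 73 at least 2-fold lower in knockout cells, together 1.19%. The median of the mean signal over both arrays was 118.9 for the higher and 147.0 for the lower genes, against 276.3 for all measured genes. Where such a gene had 2 or more measured probe sets, all of them shared the direction in 18 of 25 higher and 18 of 27 lower genes. After Mir155hg, the lowest differences among genes above the floor on both arrays were those of Ighm (immunoglobulin M heavy chain, -2.37), Jchain (the immunoglobulin joining chain, -2.24), Mrpl39, Dusp5 (a phosphatase acting on ERK kinases, -1.91, 533 against 142), the glutamate transporter gene Slc1a2 (-1.61), Kctd14 (-1.39, with 4 of 4 probe sets lower), Krtap12-1 (-1.39), Stat4 (a transcription factor of interleukin-12 signalling, -1.38, 785 against 301), Hamp (hepcidin, -1.35), Rab20 (-1.31) and Igha (-1.31, with 3 of 3 probe sets lower). Of Ighm's 8 measured probe sets, 5 were lower. Among genes above the floor only in wild-type cells, Mzb1, a B-lineage chaperone, was at least 3.75-fold lower, the basophil protease gene Mcpt8 at least 2.68-fold, the mitochondrial carrier gene Slc25a14 at least 2.62-fold and the light chain segment Igkv8-30 at least 2.49-fold lower.

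The highest difference among genes above the floor on both arrays was that of Cyp26b1, an enzyme that degrades retinoic acid, at 178 in wild-type and 763 in knockout cells (4.29-fold). Serpinb12 (1.82), Crispld2 (2.83-fold), Gask1b (1.47), Fuom (1.41), Cchcr1 (1.30), Cuedc1 (1.30, with 1 of 2 probe sets higher), Ahnak2 (1.27), Sphk1 (sphingosine kinase, 1.25), Mid1 (1.23) and Cenpo (1.21) followed on the log2 scale. The wild-type signals of Serpinb12 (68.7), Cchcr1 (69.3), Cenpo (70.4), Crispld2 (70.5), Cuedc1 (76.0), Ahnak2 (77.9) and Fuom (86.2) lay close to the floor. Those of Gask1b (92.8), Sphk1 (100.9) and Mid1 (114.9) were somewhat higher. The floor is not a detection call, so these values do not show that the genes were expressed in wild-type cells. Serpinb12, Cchcr1, Ahnak2 and Fuom had 1 measured probe set each. Cenpo's difference was -0.24 without probe sets ending in _x_at or _s_at. The value of Crispld2 came from an _x_at probe set, and its other measured probe set had a difference of 0.29. Scd2, a fatty acid desaturase, differed at a higher level, from 1420 to 3227, with 3 of 3 probe sets higher. Genes above the floor only in knockout cells included Zap70, a T-cell receptor kinase, at least 4.68-fold higher, the antisense transcript Junos, at least 4.40-fold, Gpsm2, at least 3.91-fold, and Aim2, a cytosolic DNA sensor, at least 2.91-fold higher. Junos lies antisense to Jun, and whether these probe sets tell the strands apart was not tested.

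**Figure D2:**
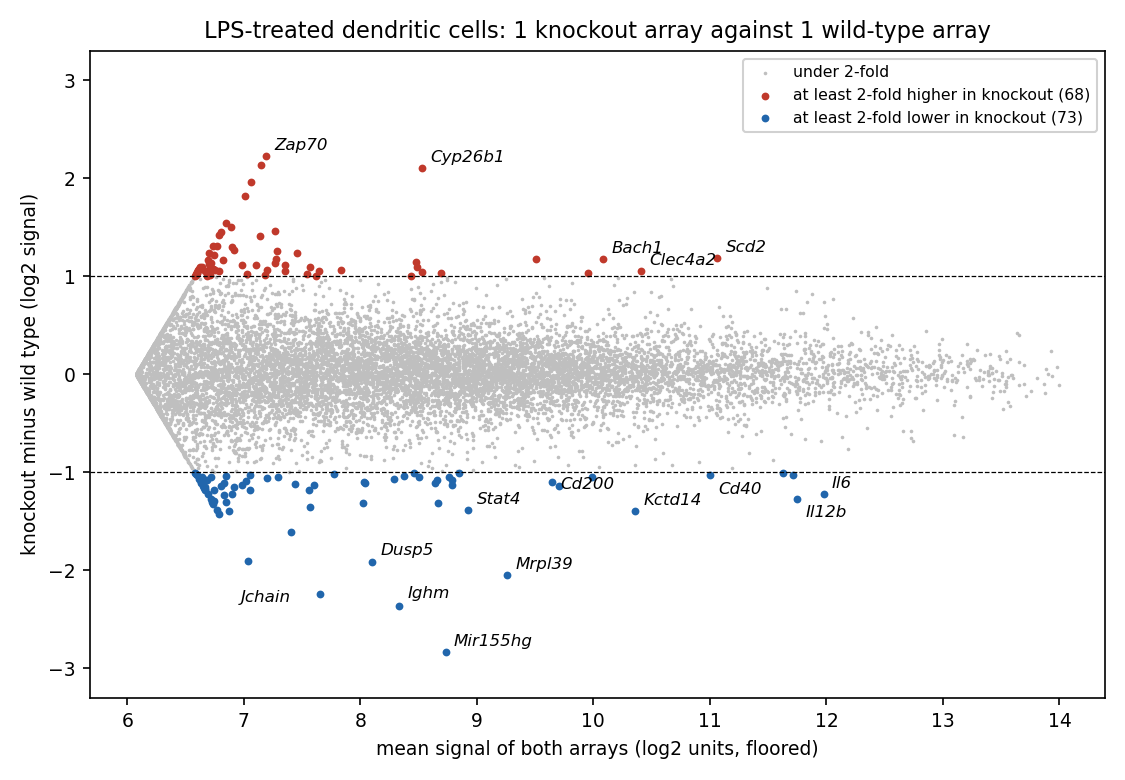
Difference between the knockout and the wild-type array (log2 signal, vertical axis) against the mean signal of both arrays (log2 units) for each of the 11878 measured genes; dashed lines mark 2-fold, and points on the slanting left edge are lower bounds with 1 array at the floor. There are 68 genes in red (higher) and 73 in blue (lower), and Il12b, Il6, Cd40 and Kctd14 are among the bright blue ones.

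Reported miR-155 targets were on balance higher in knockout cells. Of 28 measured targets, 21 were higher and 7 lower, with a median difference of 0.20 (95% bootstrap interval over genes 0.09 to 0.35), at percentile 99.9 of random lists; only Bach1 passed 2-fold. Tspan14, a tetraspanin, was 1.90-fold higher, the clock gene Arntl 1.77-fold, Inpp5d, which encodes the lipid phosphatase SHIP1, 1.52-fold (696 against 1057), Jarid2, a Polycomb cofactor, 1.42-fold with 3 of 3 probe sets higher, and Spi1, which encodes the transcription factor PU.1, 1.36-fold (777 against 1056). Cebpb had a difference of 0.12, within the probe set SD and with 1 of 2 probe sets higher, and Socs1, an inhibitor of cytokine signalling, one of -0.39. Probe sets disagreed for several of these genes: the second measured probe set had a difference of -0.32 for Inpp5d and -0.16 for Arntl. When all probe sets of a gene were averaged, the list median was 0.065, at percentile 86.0, and the list no longer stood apart. The same held with centring on the median, where the median of reported miR-155 targets was 0.11 (percentile 97.2), and with scaling on hybridisation controls (0.37, percentile 96.9). The latter settings differ from each other only by a constant shift and the floor, so they are not separate checks.

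Inflammatory and T-cell-polarising cytokine transcripts were lower in knockout cells. Of 18 measured genes 14 were lower, with a median difference of -0.50 (interval -0.64 to -0.20), below all 10000 random lists. On the deposited values the median of inflammatory and T-cell-polarising cytokines was 0.099, the median of chemokines 0.24, the median of co-stimulation and dendritic cell maturation 0.31 and the median of interferon-stimulated genes 0.40, all under the shift of 0.54, so that these groups were lower relative to the median gene and not in deposited signal. Some bright transcripts also lay under that shift, among them the Actb controls (0.07 to 0.11) and the MHC class II list (median 0.36). Lying under it therefore does not set these groups apart from genes of like level. With scaling on hybridisation controls the medians of cytokines, chemokines, maturation and interferon-stimulated genes were -0.23, -0.087, -0.013 and 0.077, under a shift of 0.23. Il12b, the p40 subunit shared by interleukins 12 and 23, was 2.41-fold lower (5331 against 2212), with 2 of 2 probe sets lower, and Il6 was 2.34-fold lower (6155 against 2634). Ebi3, a subunit of interleukin-27, was 1.74-fold lower, Tnf 1.58-fold (1858 against 1176), and Il12a, the p35 subunit of interleukin-12, 1.53-fold. Il23a was dim and at least 1.49-fold lower. Il1b (-0.17) and Ifnb1 (0.07) differed by less than the probe set SD, and Il10 lay below the floor on both arrays. Il1b (14699 against 13088) lay near the top of the signal range and Ifnb1 (81 against 85) close to the floor of 67.6. Their small differences therefore do not show that these genes were unchanged.

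Chemokines were also lower on balance, 18 of 23, with a median of -0.18 (interval -0.40 to -0.01), at percentile 0.07. Cxcl10, a ligand of CXCR3, had a signal of 4481 in wild-type and 2236 in knockout cells, Ccl7 1.68-fold and Ccl3 1.60-fold. Of 22 co-stimulation and maturation genes 16 were lower, with a median of -0.25 (interval -0.56 to -0.02), below all 10000 random lists. The co-stimulatory receptor gene Cd40 was 2.04-fold lower (2933 against 1436) and Cd80, a CD28 ligand gene, 1.72-fold lower, each with 3 of 3 probe sets, and Cd86 was 1.43-fold lower with 2 of 2. The other 2 Cd40 probe sets had smaller differences, of -0.57 and -0.55.

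Feedback inhibitors of inflammation moved the same way, with 17 of 21 lower and a median of -0.22 (percentile 0.02). Cd200, whose product restrains myeloid cells, was 2.15-fold lower, and Socs2, which is also in the maturation list, 1.94-fold lower with 5 of 6 probe sets; Arg2, an arginase, was 1.71-fold higher. In the NF-kB pathway 15 of 18 genes were lower, with a median of -0.23 (percentile 0.01): Traf1 was 1.66-fold, Nfkbiz 1.61-fold and the NF-kB subunit gene Rel 1.55-fold lower. Among 15 prostanoid, nitric oxide and oxidant enzymes, 11 were lower, with a median of -0.18 (percentile 0.40). Ptgs2 (cyclooxygenase 2) was 1.83-fold, Ptges, a prostaglandin E synthase gene, 1.63-fold and Ltc4s 1.53-fold lower.

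Of 33 measured interferon-stimulated genes, 27 were lower, with a median of -0.13 (interval -0.17 to -0.08), at percentile 0.04, and none passed 2-fold. The most different were Stat2 (1.34-fold), Ifit1 (1.27-fold) and the RNA sensor gene Ddx58 (1.27-fold, with 1 of 3 probe sets lower). Their median lay 0.37 above that of the cytokines (interval 0.07 to 0.52) and 0.12 above that of the maturation genes, with an interval that includes 0 (-0.10 to 0.44). In TLR4 signalling, the pathway that senses LPS, 10 genes were higher and 10 lower, with a median of -0.03 (percentile 23.5). Its co-receptor Cd14 had a difference of -0.43, Tab3 one of 0.41, and Inpp5d, also listed there, one of 0.60.

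**Figure D3:**
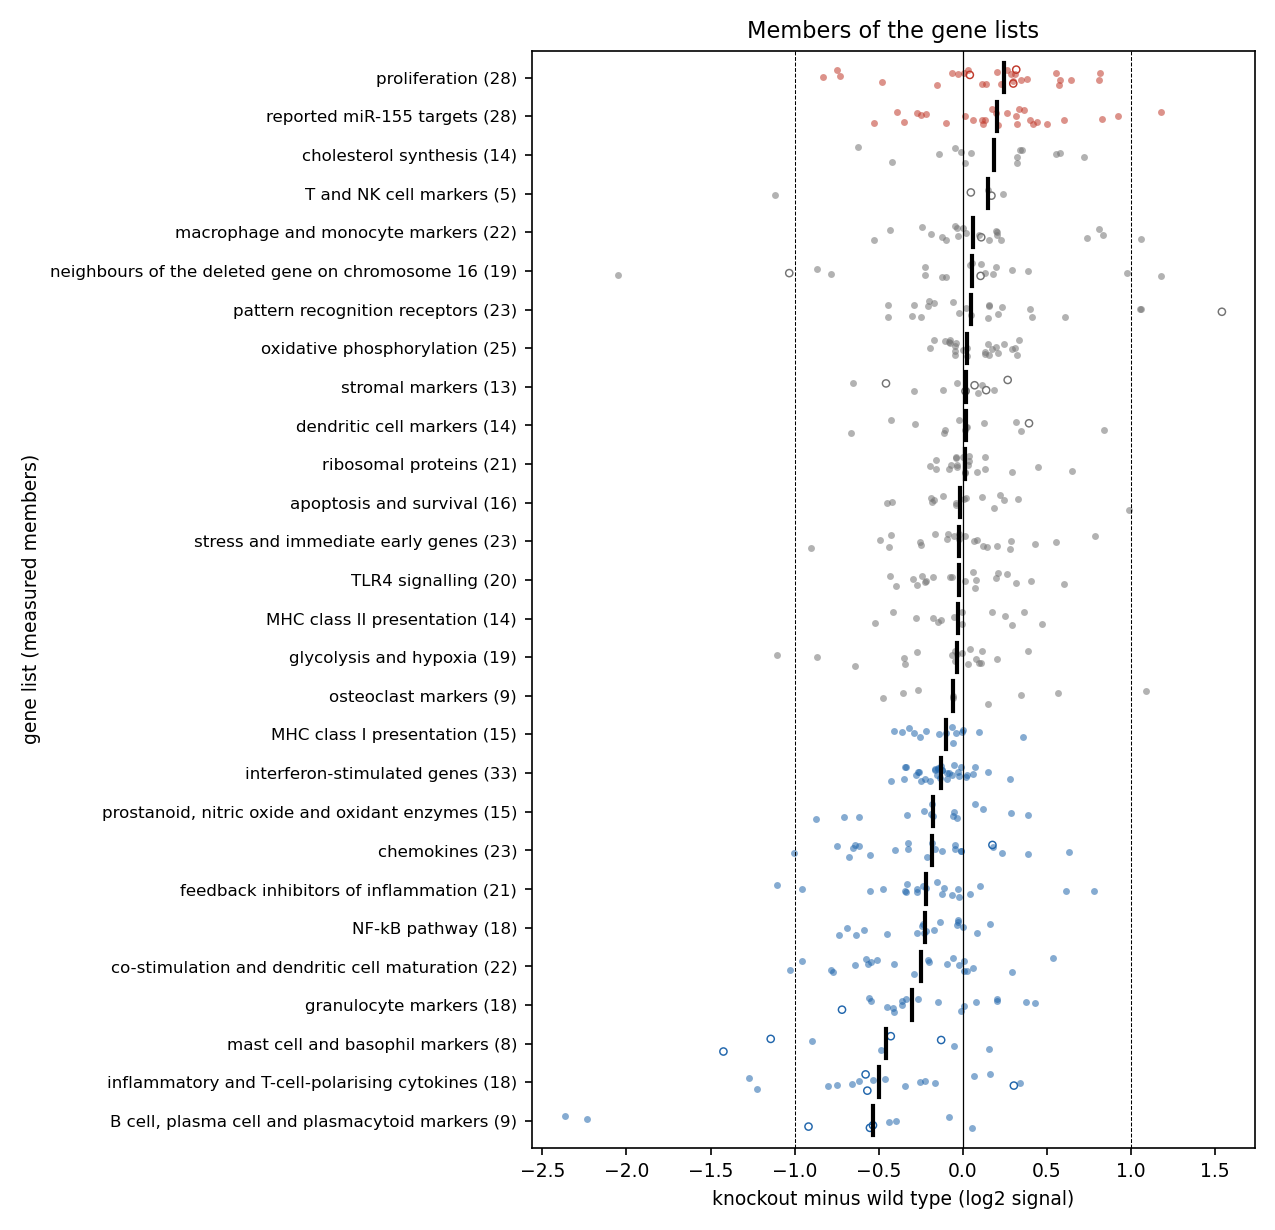
Difference between the knockout and the wild-type array (log2 signal, horizontal axis) for each measured member of the 28 gene lists (vertical axis, number measured in parentheses); open circles are lower bounds, black bars list medians and dashed lines 2-fold. Lists that stood apart from random lists are blue where lower and red where higher: cytokines lie at a median of -0.50 and reported miR-155 targets at 0.20.

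The median over 15 MHC class I presentation genes was -0.10 (percentile 2.4), and the list did not stand apart under 3 of 10 alternatives: the median of MHC class I presentation lay at percentile 2.69 with no floor, 2.6 with averaged probe sets and 9.2 against unmatched random lists. Its most different members were the peptide transporter gene Tap1 (1.33-fold lower), the regulator Nlrc5 (1.29-fold lower) and Erap1, a peptide-trimming enzyme gene (1.28-fold higher). The 14 class II genes had a median of -0.03 (percentile 24.4), but the median of MHC class II presentation depended on the scaling: it was -0.22 (percentile 0.31) with centring on the median and -0.12 (percentile 2.3) with loess, where the list stood apart. Among them H2-DMb2 was 1.44-fold lower, with 2 of 3 probe sets, Ciita, the class II transactivator gene, 1.33-fold lower, and Marchf1, a ubiquitin ligase gene, 1.39-fold higher. Pattern recognition receptors had a median of 0.05 (percentile 73.1), and 3 of 23 passed 2-fold, all higher: Aim2, the mannose receptor gene Mrc1 (2.08-fold, 138 against 288) and the lectin gene Clec4a2 (2.07-fold, 942 against 1952, with 2 of 2 probe sets).

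Markers of cell types that such cultures may hold did not move alike. Dendritic cell markers had a median difference of 0.02 (percentile 52.6), with Irf8, a transcription factor of dendritic cell development, 1.58-fold lower, Zbtb46 1.34-fold lower and Naaa 1.79-fold higher. Macrophage and monocyte markers had a median of 0.06 (percentile 80.3), but the median of macrophage and monocyte markers was 0.17 (percentile 99.8) with averaged probe sets, where the list stood apart; among them Mrc1, the chemokine receptor gene Ccr2 (1.78-fold, with 3 of 4 probe sets) and Mertk (1.75-fold) were higher. B cell, plasma cell and plasmacytoid markers were lower in 8 of 9 genes, with a median of -0.53 (percentile 0.02). Of these genes 3 were above the floor only in wild-type cells and so could count only as lower. Ighm was 5.16-fold, Jchain 4.71-fold and Spib at least 1.89-fold lower. Mast cell and basophil markers were lower in 7 of 8 genes, with a median of -0.46 (percentile 0.30). Of the 8, 4 were above the floor only in wild-type cells and so could count only as lower, among them Mcpt8 and Cpa3 (at least 2.21-fold). Hdc, the histamine-forming enzyme gene, was 1.86-fold lower, and Kit had a difference of -0.05. Granulocyte markers had a median of -0.30 (interval -0.41 to 0.04, percentile 0.04), with 12 of 18 lower, and the median of granulocyte markers was -0.13, at percentile 4.1, with the floor at the 75th percentile, where they no longer stood apart. Among the lower ones were Ltf (at least 1.65-fold), Prtn3 (1.47-fold) and Camp (1.46-fold). Among the 6 higher ones were the brighter S100a8 (4517 against 6093) and Mmp8 (3736 against 4845). The 5 measured T and NK cell markers had a median of 0.15 (percentile 94.4), with Thy1 2.17-fold lower, Cd8a at 0.24 (1 of 2 probe sets) and Cd4, above the floor only in knockout cells, at least 1.13-fold higher. Stromal markers had a median of 0.02 (percentile 57.3), with Thbs1 and Col1a2 at -0.65 and -0.29 and Lum at least 1.37-fold lower, and osteoclast markers one of -0.06 (percentile 22.4), with Ctsk (cathepsin K) 2.13-fold higher, Atp6v0d2 1.48-fold higher and Tnfrsf11a 1.39-fold lower. Only 4 erythroid markers were measured, of which Car2, a carbonic anhydrase gene, was 2.04-fold lower, Epor had a difference of -0.57 and Tfrc one of 0.22, with 1 of 2 probe sets higher. Xist, the only sex-linked transcript measured, had signals of 2271 and 1810 (difference -0.33, with 2 of 3 probe sets lower), and Eif2s3y, Kdm5d and Uty lay below the floor on both arrays.

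Proliferation genes were higher in 21 of 28 cases, with a median of 0.25 (interval 0.04 to 0.31), at percentile 99.97. The nucleotide reductase gene Rrm2 was 1.76-fold higher with 3 of 3 probe sets and the replication helicase gene Mcm4 1.76-fold higher with 2 of 2, whereas Cdc20, an activator of mitotic exit, was 1.78-fold lower. The other probe sets had smaller differences, of 0.37 each for Rrm2 and 0.17 for Mcm4. Cholesterol synthesis genes had a median of 0.18 (percentile 97.3), with Lss 1.64-fold and Stard4 1.49-fold higher and Idi1 1.54-fold lower with 1 of 2 probe sets. The control probe sets for 18S ribosomal RNA, a sign of RNA preparation, had deposited signals of 95.1 to 126.1 on the wild-type and 389.2 to 581.9 on the knockout array. The ratio of the 3' to the 5' control probe set, a sign of RNA integrity, was 1.28 and 1.25 for Actb and 0.84 and 0.88 for Gapdh in wild type and knockout.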

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

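The tests of the 3 patterns below, with their limits and windows, were chosen after differences of the genes that raised each pattern had been seen on the same arrays, although the loess that serves the first pattern had been chosen as a processing step to try before the data were examined, and the removal of Ighmbp2 from the immunoglobulin probe sets followed a first look at their median. Control probe sets for 18S ribosomal RNA, which no comparison used, had a median log2 difference of 1.37 in the knockout array relative to all probe sets. Probe sets unnamed here held 16 that were at least 2-fold higher and 20 that were at least 2-fold lower among 3326 measured (1.08%, against 1.30% of probe sets that name 1 gene).

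The first pattern is that cytokine and maturation transcripts were lower in the knockout array. Compression of bright signals on the brighter array would give a difference that disappears once the trend with level is removed. After a loess the cytokine median was -0.50 (95% interval over genes -0.61 to -0.25), and the maturation median was -0.25 (interval -0.56 to -0.06), below all random lists. The maturation limit replaced a stricter one after the value was seen because the median before the loess could not have met it. The pattern was first seen after quantile normalization, which forces both arrays to one distribution and so already acts on such a trend. The loess, applied to the deposited values instead, could therefore hardly differ. It shows only that the lower medians did not depend on which of these scalings was used. The median of the interferon-stimulated genes lay 0.37 above that of the cytokines (interval 0.07 to 0.52) and 0.12 above that of the maturation genes (interval -0.10 to 0.44). A uniformly weaker response to LPS stays open for both lists, since without untreated cells it is not known how far LPS induced each of them. A difference between the cultures in cell composition, maturation or timing stays open for both lists, since each genotype was 1 sample. In the same array, markers of mast cells and basophils (-0.46) and B and plasma cells (-0.53) were lower and the 18S controls higher (1.37). Granulocyte markers had a median of -0.30, but its interval (-0.41 to 0.04) included 0 and 6 of 18 were higher.

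The second pattern is the set of differences at genes beside the deleted gene. A local effect around the altered allele was tested on the 20 nearest measured genes, equal numbers on each side and without Bach1, whose root mean square difference of 0.68 lay at percentile 99.9 of 11100 overlapping windows on other chromosomes (median 0.33); it was 0.51 without Mrpl39 (percentile 98.4) and 0.46 without Mrpl39 and Jam2 (percentile 95.9), but this window holds the genes that raised the pattern, so the percentile decides nothing. The next 60 genes had 0.35. Strain variants under single probe sets would set probe sets of a gene against each other, but all 4 changed genes of this window with several measured probe sets (Nrip1, Usp25, Mrpl39 and Jam2, of which the former pair were chosen after their values were seen) had every probe set on 1 side, whereas the other probe set of Bach1, outside the window, had a difference of -0.28 against 1.18, so that such a variant stays open there. It also stays open for Samsn1 (-0.87), Zfp654 (0.71) and Robo1 (0.67), changed genes of the window with 1 measured probe set each. An effect of the allele on adjacent genes stays open, and expression differences carried by flanking DNA of another strain were not tested; for Bach1, target repression, position and a variant cannot be told apart.

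The third pattern is that immunoglobulin and plasma cell transcripts were lower in the knockout array. Fewer plasma cells in the knockout culture could lower them together: 17 of 21 immunoglobulin probe sets were lower, with a median of -0.35 (interval -1.31 to -0.07), but of 14 other plasma cell genes only 7 were lower (median -0.002), and several of these, such as Xbp1 and Edem1, are also expressed by dendritic cells. Jchain, Mzb1 and Pou2af1 (at least 0.69 log2 units lower, chosen after its value was seen) were the lowest of them. Cross-hybridisation was examined through probe sets marked as shared between genes (names ending in _x_at or _s_at). In the list of B cell, plasma cell and plasmacytoid markers 0 of 9 measured genes was read from such a probe set. Its median of -0.53 (interval -2.24 to -0.08, percentile 0.01) therefore did not come from them, and leaving them out could not change it. Cross-hybridisation of probe sets without such names was not tested, and some of those name several genes. For the immunoglobulin probe sets as a class cross-hybridisation stays open. The 8 without such names were all lower, Igha (419 to 44) and Ighm (734 to 142) by far the most, but had a median of -0.19 (interval -2.37 to -0.07). It too is a lower bound on the fall, since several of the 8 had knockout signals below the floor. For other Ighm probe sets among them the differences of -0.01 and -0.08 are lower bounds set by the floor. Their wild-type signals (68.1 and 71.5) lay just above it and their knockout signals (35.4 and 26.9) below it. They therefore do not show how far these probe sets changed. Probe sets of the same gene were counted separately here and among the 21, so these counts and intervals are not over independent genes. Fewer plasma cells and an effect of the genotype cannot be told apart, since each genotype was 1 culture.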

How the results depend on the processing

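The deposited scale and the scaling on hybridisation controls were added after the data were seen. Counts of 2-fold genes (68 higher, 73 lower) depended on the floor, the scaling and the threshold. They were 504 and 508 with the floor at the 25th percentile, 11 and 25 at the 75th, 1288 and 1304 with no floor, 543 and 487 at 1.5-fold, and 5 and 7 at 3-fold. Without scaling they were 855 and 12 (98.6% higher), and with scaling on hybridisation controls 181 and 33 (84.6%); these leave the median of all genes at 0.54 and 0.23, and relative to those medians the counts were 47 and 112, and 53 and 93. With centring on the median they were 54 and 86 (38.6% higher, against 48.2%), and with loess, averaged probe sets or fewer probe sets they stayed within 1.5 times. The SD between probe sets was 0.22 with the floor at the 75th percentile. The cytokine, chemokine, maturation and interferon lists stood apart under all 10 alternatives, with medians of -0.58 to -0.46, -0.34 to -0.15, -0.30 to -0.21 and -0.17 to -0.10 under the planned ones. The deposited scale, the scaling on hybridisation controls and centring differ from one another only by a constant shift and the floor. A percentile can hardly change between them, so tallies over the 10 alternatives do not count independent checks. The median of reported miR-155 targets stood apart under 7 of 10 and was 0.065 (percentile 86.0) with averaged probe sets, where disagreeing probe sets enter, 0.11 (percentile 97.2) with centring and 0.37 (percentile 96.9) with scaling on hybridisation controls. The median of MHC class II presentation stood apart under 4 of 10 alternatives, among them centring (-0.22, percentile 0.31) and loess (-0.12, percentile 2.3), the class I list under 7, and granulocyte markers under 9. When probe sets were averaged, 4 lists stood apart that otherwise did not: the median of macrophage and monocyte markers was 0.17 (percentile 99.8), the median of oxidative phosphorylation 0.12 (98.97), the median of cholesterol synthesis 0.20 (99.1) and the median of pattern recognition receptors 0.14 (98.4). Of the named genes past 2-fold, only Cenpo changed sign, to -0.24 without _x_at and _s_at probe sets. The cause of these changes was not tested beyond what each setting's construction shows. No replicate could be left out, and no paired analysis was possible because each group held 1 array. The planned comparison of seed-site genes was not run.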

Other observations

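Oxidative phosphorylation genes had a median difference of 0.02 (percentile 55.2 of random lists), with Uqcrc1, Ndufb5 and Cox5a at 0.34, 0.32 and 0.31. The median of oxidative phosphorylation was 0.12, at percentile 98.97, when all probe sets of a gene were averaged, and the list then stood apart. Ribosomal protein genes had a median of 0.01 (percentile 52.7), with Rps6, Rpl37 and Rps9 at 0.65, 0.45 and 0.29, the last with 2 of 3 probe sets higher. Glycolysis and hypoxia genes had a median of -0.03 (percentile 21.9). Among them Vegfa, an angiogenic growth factor gene, was 2.15-fold lower at the probe set used, while its other measured probe set had a difference of -0.06. The lactate exporter gene Slc16a3 was 1.82-fold lower. The oxygen sensor gene Egln3 was 1.56-fold lower at 1 of 2 probe sets, the other having a difference of at least 0.42. Stress and immediate early genes had a median of -0.02 (percentile 28.3), with the growth arrest gene Gadd45a 1.87-fold lower and the transcription factor genes Egr2 and Egr1 1.73-fold and 1.47-fold higher. Apoptosis and survival genes had a median of -0.02 (percentile 31.4), with Pmaip1, a pro-apoptotic BCL2 family gene, 1.98-fold higher, Casp8 1.37-fold lower and the cell cycle inhibitor gene Cdkn1a 1.34-fold lower.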
